A study of Homo sapiens with 12 samples.

How the data were processed

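MCF10A, an immortalised human mammary epithelial line, was transfected with control siRNA at 22 nM or with siRNA sets against YAP and TAZ at 11 nM, and 48 h later received DMSO or 5 µM XMU-MP1, an inhibitor of the MST1 and MST2 kinases, for 6 h. The 4 groups of 3 libraries are called siC_DMSO, siC_XMU, siYT_DMSO and siYT_XMU below, with the submitters' letters a, b and c for the libraries. Per the labels, polyadenylated RNA was made into stranded paired-end libraries and sequenced on a NovaSeq instrument. The submitters' notes name cutadapt, FastQC, HISAT2, StringTie and edgeR and the build GRCh38.p13, without versions, roles or settings.

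The deposited table holds, per the file headers, whole-number counts and FPKM values for 46931 genes in each of the 12 libraries, which is 24 columns of values, all of which were used. The authors gave the count columns unscaled, and how the reads were counted is not stated. The authors also gave FPKM, that is fragments per kilobase of transcript scaled to the depth, and every gene with a count of 0 has an FPKM of 1e-04 there. Positions are those of the table, RefSeq coordinates on GRCh38.p13 counted from 1. Of the table's symbols 667 are duplicated, and 1713 entries lie on unplaced or alternate scaffolds. Values are per gene, so the TA and deltaN transcripts of TP63 are not told apart.

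Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 18143, libraries were scaled by TMM, and a quasi-likelihood model with 4 group means was fitted to all 12 libraries, with 8 residual degrees of freedom, a common dispersion of 0.232 and 3.85 prior degrees of freedom. The design, written before the data were examined, planned limma-trend on FPKM and named this edgeR model for the case that the table held counts. Log2 fold changes carry edgeR's prior count of 0.125, and their standard error (SE) was taken as the size of the log2 fold change divided by the square root of the F statistic. A gene is called where its Benjamini-Hochberg adjusted p lies under 0.05 over the genes tested, and tests of genes are two-sided. Levels are CPM, edgeR's counts scaled to library size, with TMM scaling, as mean ± SD of 3 libraries. The 5 contrasts were the siRNA against YAP and TAZ (below, the knockdown) in DMSO and in XMU-MP1, XMU-MP1 in each siRNA arm, and the interaction, which is the XMU-MP1 effect in the knockdown arm minus that in the control arm. For TP63, YAP1 and WWTR1 an exact two-sided permutation test of 3 against 3 libraries, whose smallest possible p is 0.1, was added.

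Depth ranged from 8243351 to 67953633 counts per library. A count of 0 allows up to 3 counts, which is 0.0382 to 0.622 CPM. Where all libraries of a group were at 0 the fold is given as a lower bound against this floor of 3 counts per library. Such floors cover counting error only. Whether the letters stand for separate cultures is not stated, so the p-values measure the spread between these samples. No sequencing batch is given. Correlations of residuals between groups within a letter were weak, with 2 of 18 over 0.1 (range -0.02 to 0.17). Still, 11 of 12 libraries correlated best with their own letter, so a weak effect shared by a letter is not excluded. The main fit leaves the letters out, and a replicate block was tried as an alternative. TMM assumes that most genes do not change, and no spike-in is in the table.

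In simulated data made from these libraries, 100 of 18143 genes were changed 2-fold and another 100 were changed 4-fold. The edgeR model called between 10 and 18% of genes at a 2-fold change and between 64 and 66% at 4-fold in the group comparisons. For the interaction it called 0% at 2-fold and 36% at 4-fold. It called at most 2 unchanged genes. So few changed genes make the adjusted threshold strict, so these shares may be too low where many more genes change.

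The 29 gene lists were fixed before the data were examined and were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run as alternatives. Calls within a list are given over all genes tested and adjusted over the list alone. None of the lists was chosen on these samples. GO terms in the table were tested with the one-sided hypergeometric test against the tested genes that carry a term, after the data were seen.

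Genes are named by a rule also fixed before the data were examined. It names 9 genes in every comparison (YAP1, WWTR1, STK3, STK4, LATS1, LATS2, TP63, CCN1 and CCN2). Outside the knockdown in XMU-MP1 it adds the 6 largest positive and the 6 largest negative called changes of genes whose name is not a bare identifier, with a mean FPKM of at least 5 in the higher group and, between groups, no overlap of libraries. It also adds up to 4 called members with the smallest adjusted p of each list that passed camera or had at least 3 called members.

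The settings also tried were no filter, a filter on FPKM of at least 5, total counts without TMM, median-ratio size factors, quantile normalisation, DESeq2 1.42.0, a fit of only the compared groups, a robust variance model, a variance model without an abundance trend, a replicate block, and leaving out each library in turn. Added as alternatives after the data were seen were limma-trend on log2 FPKM with pseudocounts of 0.5, 0.1 and 1, voom with quality weights, and leaving out the 22 ribosomal RNA genes and SLCO5A1 before scaling. The first group was fixed before the data were examined. Gene counts without library c of siYT_XMU, which stands apart, are given beside the main ones, and so are counts of list members where they moved by over 1.5 times. Where leaving out any 1 library moved such a count by over 1.5 times, its range over the 12 libraries is given.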

Results

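Gene expression was measured by RNA sequencing in 12 libraries of MCF10A cells, 3 in each of the groups siC_DMSO, siC_XMU, siYT_DMSO and siYT_XMU. The series title concerns a non-canonical Hippo pathway that represses deltaNp63, a transcript form of TP63. In the Hippo pathway the kinases MST1 and MST2 (genes STK4 and STK3) act through LATS1 and LATS2 to restrain the coactivators YAP (gene YAP1) and TAZ (gene WWTR1), and XMU-MP1 inhibits MST1 and MST2. Total counts, in libraries a, b and c, were 55975525, 67953633 and 62607442 in siC_DMSO and 46901372, 52872029 and 57817609 in siC_XMU. They were 25246464, 48112769 and 58389794 in siYT_DMSO and 37044804, 60832492 and 8243351 in siYT_XMU. Library c of siYT_XMU stood apart. Ribosomal RNA took 35.0% of its counts, most of it mitochondrial (26.4% against 8.52% nuclear), and the gene SLCO5A1 12.6%. In every library the mitochondrial part was the larger. It had counts for 15135 genes against 17950 to 20704 in the other libraries, and its second principal component score was -205 against -51.8 for the next lowest library. Ribosomal RNA took between 1.02 and 2.52% of counts in the 6 control siRNA libraries and between 1.86 and 8.35% in the other 5 libraries of the YAP and TAZ siRNA. The first principal component (40.7% of the variance) separated the siRNA arms, with scores of at most -95.1 in control siRNA and at least 69.8 after the knockdown.

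**Figure D1:**
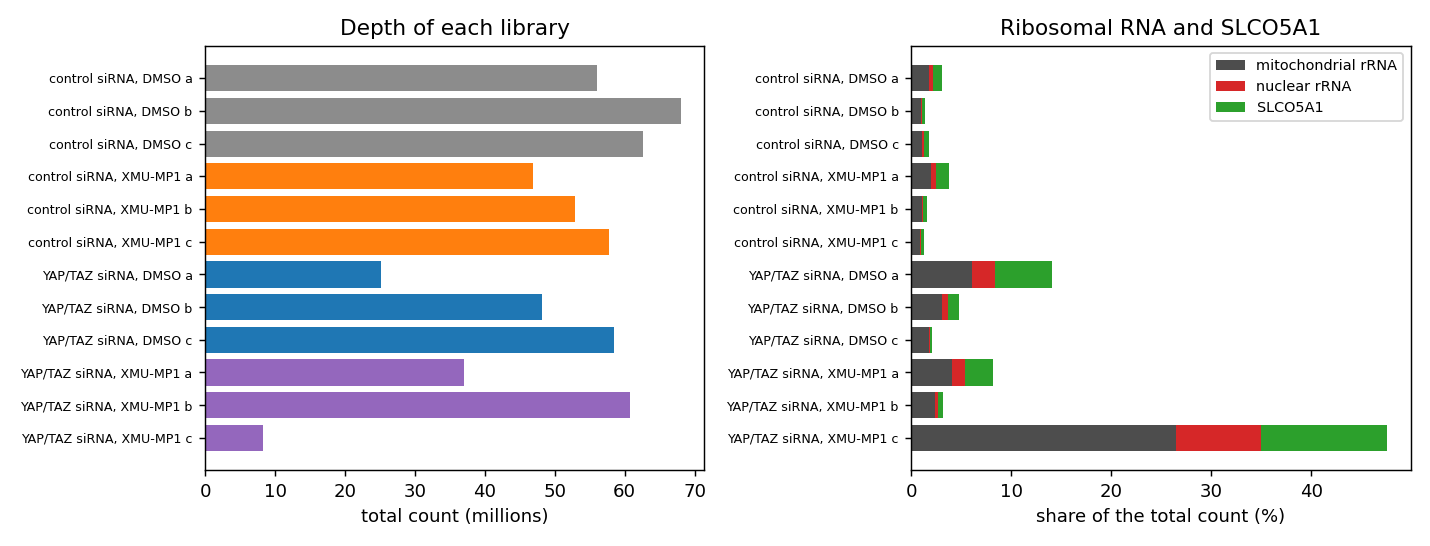
Total count per library, and the share of counts taken by ribosomal RNA and by SLCO5A1 in percent, for the 12 libraries. Library c of siYT_XMU has 8243351 counts, of which 35.0% are ribosomal RNA and 12.6% SLCO5A1.

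The knockdown in DMSO asks what the loss of YAP and TAZ changed without the inhibitor, and its targets come first. YAP1 (ID 10413, chromosome 11, 102109957 to 102233424, plus strand) stood at 201, 223 and 193 CPM in siC_DMSO and at 12.6, 9.09 and 7.84 CPM in siYT_DMSO, a fall of 20.9-fold (log2 fold change -4.39, SE 0.24, adjusted p = 8.41e-07). WWTR1 (ID 25937, chromosome 3, 149517229 to 149724788, minus strand) stood at 34.6, 24 and 38.2 CPM in siC_DMSO and at 4.30, 4.47 and 3.66 CPM in siYT_DMSO (-2.96, SE 0.47, adjusted p = 0.000511). With XMU-MP1, YAP1 stood at 132, 135 and 142 CPM in siC_XMU and at 6.63, 3.81 and 5.39 CPM in siYT_XMU, and WWTR1 at 56.9, 60.3 and 56.0 CPM in siC_XMU and at 2.11, 1.24 and 0 CPM in siYT_XMU. A count of 0 in library c of siYT_XMU allows up to 0.622 CPM. Every knockdown library lay below every control library for both genes. By chance 10% of splits of 3 against 3 separate fully in either direction. The exact two-sided permutation p was 0.1 for each gene in each pair of groups, the smallest possible.

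**Figure D2:**
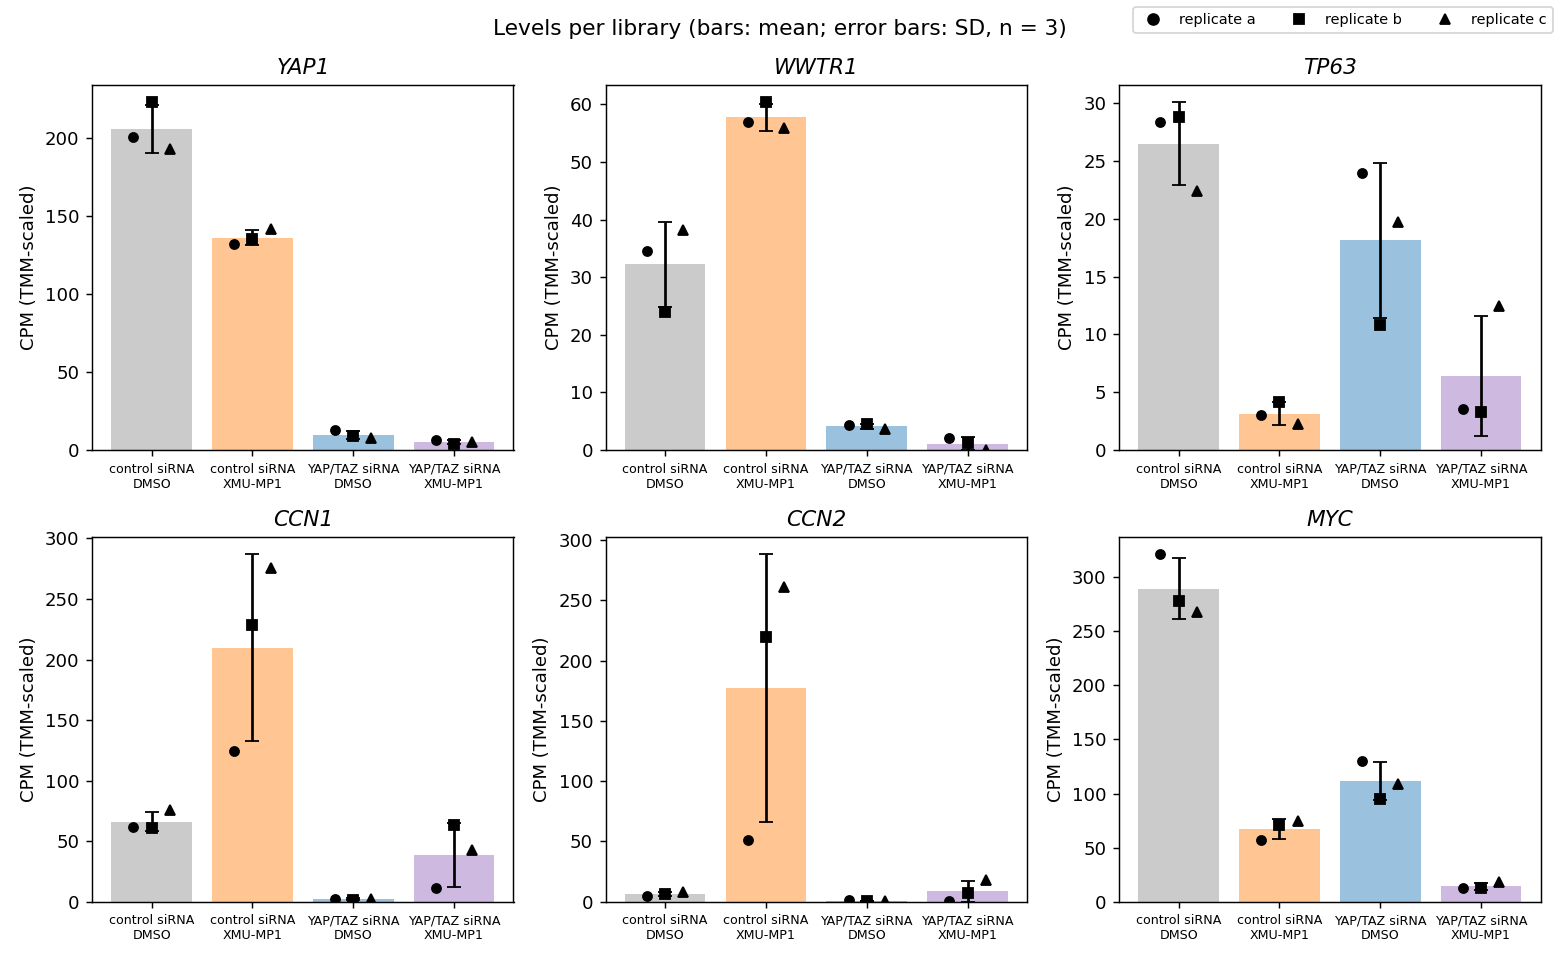
Level in CPM of YAP1, WWTR1, TP63, CCN1, CCN2 and MYC in each library by group, with bars for the mean ± SD (n = 3). TP63 has a mean of 26.5 CPM in siC_DMSO and 3.14 CPM in siC_XMU, while in siYT_XMU library c (12.4 CPM) lies above the other 2 libraries (3.58 and 3.25 CPM).

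After the knockdown in DMSO, genes of the outer, cornifying epidermis rose, and genes of the cell cycle fell. Of 22 tested epidermal differentiation genes, 18 rose and 0 fell over all genes tested (19 adjusted over the list alone), with a median log2 fold change of 5.41, or 5.34 with genes absent from a group at their bound. SPRR1B, a cornified envelope protein, rose from 6.41 ± 1.40 to 1970 ± 508 CPM (8.26, adjusted p = 7.64e-07). S100A7, a calcium-binding protein of keratinocytes, rose from 16.7 ± 4.26 to 5042 ± 1090 CPM (8.24, adjusted p = 8.33e-07), and CNFN, cornifelin, to 481 ± 195 CPM (8.90, adjusted p = 1.58e-06). All 30 genes of G2/M and mitosis fell (also 30 adjusted over the list alone, median -4.22), as did 27 of 28 of G1/S and DNA replication (27 over the list alone, median -3.70). KIF20A, a mitotic kinesin, fell from 262 ± 42.5 to 8.85 ± 4.24 CPM, PCNA, the replication clamp, from 160 ± 5.07 to 14.7 ± 0.404 CPM, and MCM3, a part of the replicative helicase, from 240 ± 11.3 to 18 ± 5.06 CPM. Camera gave adjusted p values of 1.82e-24 for the epidermal list, 8.13e-39 for G2/M and 6.25e-33 for G1/S, and for each of the 3 lists the adjusted p = 0.0733 with an estimated correlation. The share of ribosomal RNA moved with these groups, from 2.15, 1.05 and 1.32% in siC_DMSO to 8.35, 3.64 and 1.86% in siYT_DMSO. S100A8 and S100A9, members of the epidermal list that leukocytes also make, rose by 6.66 and 5.34 on the log2 scale, and of 4 tested leukocyte markers 2 rose (2 over the list alone, camera adjusted p = 0.156).

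Known targets of YAP and TAZ fell with them. Of 22 tested signature genes 15 fell and 0 rose (18 adjusted over the list alone), with a median of -1.66, or -1.59 with bounds, and a camera adjusted p of 1.33e-07 (adjusted p = 0.0733 with an estimated correlation). CCN1 (ID 3491, chromosome 1, 85580761 to 85583950, plus strand), a matricellular protein, fell from 66.1 ± 8.04 to 2.04 ± 0.826 CPM (-5.03, SE 0.60, adjusted p = 8.04e-05). CCN2 (ID 1490, chromosome 6, 131948176 to 131951372, minus strand), a related protein, fell from 6.42 ± 2.02 to 0.717 ± 0.320 CPM (-3.23, SE 0.87, adjusted p = 0.014), though its adjusted p became 0.0606 and 0.0572 without library b or c of siYT_DMSO and 0.124 with voom. AMOTL2, a scaffold that binds YAP, fell from 88.7 ± 23.3 to 10.5 ± 3.01 CPM. Among 29 tested components of the Hippo pathway 4 rose and 13 fell (6 and 15 adjusted over the list alone, median -0.75, camera adjusted p = 0.00107, adjusted p = 0.263 with an estimated correlation). The list holds YAP1 and WWTR1, the targets of the siRNA, which count among the falls and enter the camera test. TEAD4, a DNA-binding partner of YAP, fell by 3.25 on the log2 scale and its relative TEAD3 rose by 2.04. STK3 (ID 6788, chromosome 8, 98433048 to 98944329, minus strand) fell by 1.84 (SE 0.21, adjusted p = 6.27e-05) and LATS2 (ID 26524, chromosome 13, 20973036 to 21061549, minus strand) by 1.65 (SE 0.26, adjusted p = 0.000532). STK4 (ID 6789, chromosome 20, 44966470 to 45080021, plus strand; -0.27, adjusted p = 0.54) and LATS1 (ID 9113, chromosome 6, 149658153 to 149718256, minus strand; -0.46, adjusted p = 0.421) did not pass the test.

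Further lists moved in DMSO after the knockdown. Of 24 ribosome biogenesis genes 17 fell and 0 rose (21 adjusted over the list alone, median -1.52, camera adjusted p = 1.69e-11, adjusted p = 0.164 with an estimated correlation). NOP58, a protein of small nucleolar particles, changed by -3.23. MYC, a regulator of growth, fell from 289 ± 28.3 to 111 ± 17.5 CPM (-1.38, adjusted p = 0.000161). Of 12 replication-dependent histone genes 7 rose and 0 fell (7 over the list alone, median 2.14, camera adjusted p = 5.49e-07, adjusted p = 0.0733 with an estimated correlation). Leaving out any 1 library, 0 to 1 histone genes fell. H2BC4 rose from 3.31 ± 0.339 to 160 ± 50.5 CPM. Histone genes have near-identical copies, and some of these are known to make polyadenylated transcripts too. Of 24 immediate early and AP-1 genes 13 rose and 3 fell (14 and 3 over the list alone, median 1.36, camera adjusted p = 0.000172, adjusted p = 0.0733 with an estimated correlation). FOS rose from 7.78 ± 1.96 to 64.7 ± 24 CPM and JUNB from 76.6 ± 12.5 to 419 ± 47.2 CPM. Of 21 cytoskeletal targets of SRF and MRTF 12 fell and 0 rose (12 over the list alone, median -0.71, camera adjusted p = 0.000471, adjusted p = 0.307 with an estimated correlation). Of 24 genes of ATF4 and the unfolded protein response 2 rose and 13 fell (2 and 14 over the list alone, median -0.86, camera adjusted p = 0.0177, adjusted p = 0.651 with an estimated correlation). That call ended on FPKM with a pseudocount of 0.1 (adjusted p = 0.0665) or 1 (adjusted p = 0.134).

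The other lists did not pass camera in the knockdown in DMSO, although members of most of them were called one by one. Of 30 p63 targets 10 rose and 5 fell (10 and 6 adjusted over the list alone, camera adjusted p = 0.385), with a median of -0.16 and a mean of 0.21, so that median and mean differ in sign. CSTA, a protease inhibitor of keratinocytes, rose by 3.38 and KRT5, a basal keratin, fell by 1.59. Basal mammary and hemidesmosome markers had 2 higher and 4 lower of 21 (2 and 4 over the list alone, adjusted p = 0.204), and luminal mammary markers 5 and 4 of 18 (6 and 5, adjusted p = 0.738). Genes of mesenchymal transition had 1 and 7 of 19 (1 and 8, adjusted p = 0.0896), the TGF-beta response 1 and 6 of 22 (1 and 6, adjusted p = 0.156, 2 and 6 without siYT_XMU c), Wnt targets 0 and 2 of 10 (0 and 2, adjusted p = 0.0742) and Notch targets 4 and 4 of 12 (4 and 4, adjusted p = 0.512). NOTCH3, a Notch receptor, rose from 1.03 ± 0.421 to 137 ± 10.3 CPM, and COL4A1, a basement membrane collagen, fell from 91.9 ± 34.3 to 4.38 ± 1.64 CPM. The p53 targets had 5 and 6 of 25 (6 and 7, adjusted p = 0.354), the type I interferon response 4 and 5 of 23 (4 and 5, adjusted p = 0.669), NF-kB and inflammatory cytokines 5 and 8 of 23 (5 and 8, adjusted p = 0.286) and ERK feedback genes 7 and 4 of 19 (7 and 4, adjusted p = 0.512). Cholesterol synthesis had 6 and 2 of 21 (6 and 4, adjusted p = 0.657, 6 and 4 without siYT_XMU c), heat shock 3 and 5 of 18 (3 and 6, adjusted p = 0.354), hypoxia and glycolysis 5 and 3 of 19 (5 and 3, adjusted p = 0.385) and NRF2 targets 7 and 5 of 20 (8 and 6, adjusted p = 0.385). Fibroblast markers had 1 and 1 of 8 (1 and 1, adjusted p = 0.677, 2 and 1 without siYT_XMU c) and endothelial markers 0 and 0 of 5 (0 and 0, adjusted p = 0.811, 1 and 0 of 7 without siYT_XMU c). The mitochondrially encoded list had 0 members in the table. With any 1 library left out, the higher counts ranged from 3 to 6 for luminal markers, p53 targets and cholesterol synthesis, and from 0 to 2 for mesenchymal transition and TGF-beta. They ranged from 2 to 4 for interferon, 1 to 5 for NF-kB, 4 to 7 for ERK feedback, 3 to 7 for hypoxia, 1 to 2 for fibroblast and 0 to 1 for endothelial markers. The lower counts ranged from 3 to 7 for interferon, 5 to 8 for NF-kB, 2 to 5 for ERK feedback, 2 to 4 for Wnt targets and 1 to 4 for cholesterol synthesis.

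Among genes whose name is not a bare identifier, with a mean FPKM of at least 5 in the higher group and no overlap of libraries, the 6 largest rises in DMSO were all from 0 counts in each siC_DMSO library. CERS3, a ceramide synthase of the skin barrier, was at least 983-fold higher (41.1 ± 20.3 CPM in siYT_DMSO), and SLC5A1, a sodium and glucose transporter, at least 774-fold. CARD18 was at least 556-fold higher, CRCT1 at least 490-fold, CYP4F22, a fatty acid hydroxylase of the skin barrier, at least 459-fold and ACP5 at least 362-fold. The largest falls by the same rule included THBS1, thrombospondin, from 419 ± 78.9 to 5.67 ± 3.67 CPM, MCM10, a replication factor, from 43.9 ± 0.984 to 0.984 ± 1.05 CPM, and NEIL3, a DNA glycosylase, from 22.2 ± 3.25 to 0.396 ± 0.236 CPM. CHCHD10 was at least 166-fold lower in siYT_DMSO, with 0 counts in its 3 libraries, but its level in siYT_XMU was 13.5, 0 and 13.9 CPM, with nothing between. How reads were assigned to genes is not stated, so these values of 0 need not be an absence of the transcript. FAM72C, which has near-identical copies, stood at 0, 0.232 and 0.0662 CPM in siYT_DMSO and SFTA1P at 0, 0 and 0.199 CPM, against a mean floor of 0.0776 CPM there, so no fold is given for them. In all, 2929 genes rose and 2897 fell of 18143 tested with edgeR, 2136 and 2132 of them by at least 2-fold. Without library c of siYT_XMU 3487 rose and 3612 fell.

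**Figure D3:**
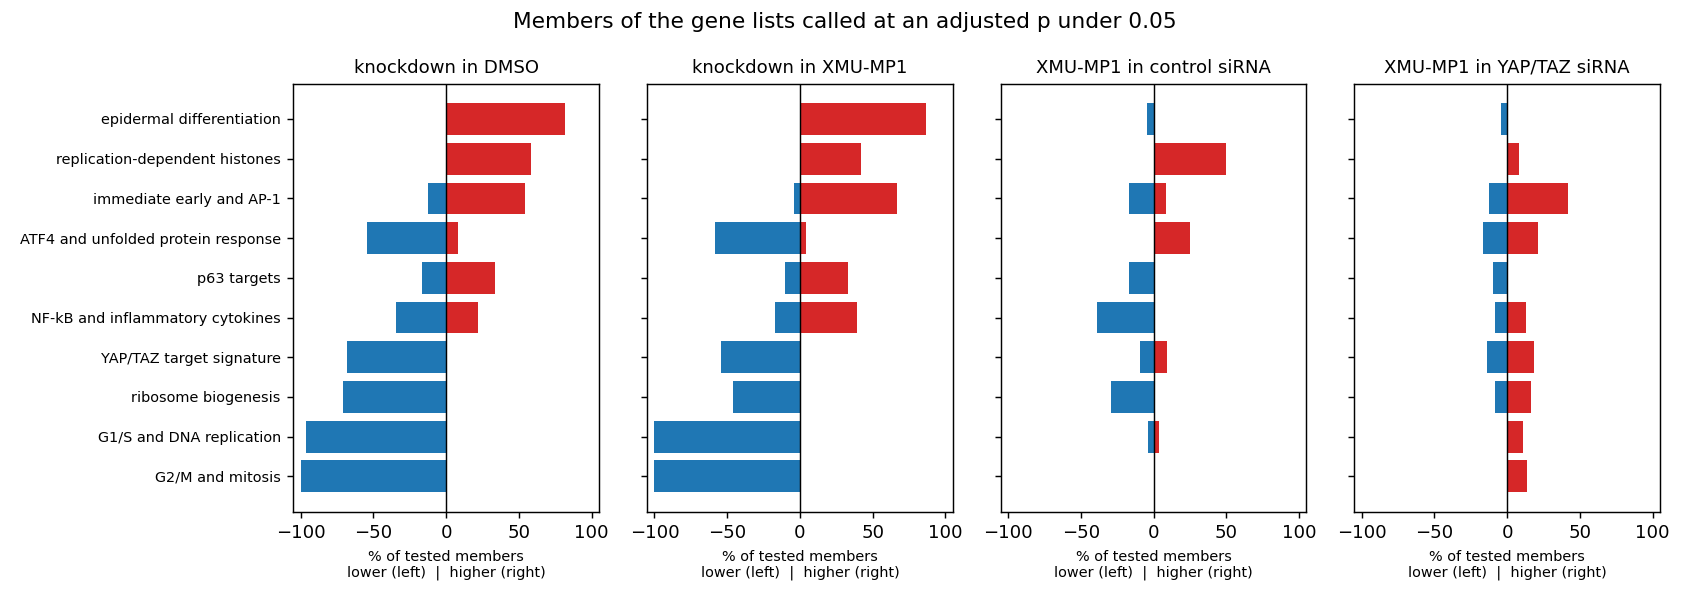
Share of tested members called higher and lower, in percent, for 10 gene lists in the 4 group comparisons. The epidermal list is higher (18 and 19 of 22 members) and the G2/M list lower (30 of 30) in both knockdown comparisons.

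XMU-MP1 in control siRNA asks what inhibiting MST1 and MST2 for 6 h changed with YAP and TAZ present. TP63 fell, and the YAP and TAZ target CCN2 rose. TP63 (ID 8626, chromosome 3, 189596746 to 189897279, plus strand), which encodes a transcription factor of basal epithelial cells, stood at 28.3, 28.8 and 22.4 CPM in siC_DMSO and at 3.03, 4.17 and 2.22 CPM in siC_XMU (-3.08, SE 0.51, adjusted p = 0.00415). Its exact permutation p was 0.1, the smallest possible. CCN2 rose from 6.42 ± 2.02 to 177 ± 111 CPM (4.79, SE 0.87, adjusted p = 0.00672). CCN1 stood at 66.1 ± 8.04 CPM in siC_DMSO and 210 ± 77.3 CPM in siC_XMU and did not pass the test (1.67, SE 0.51, adjusted p = 0.067). It passed with no filter (adjusted p = 0.0449), in the fit of the compared groups (0.00731), with DESeq2 (0.0102) and voom (0.0016), and without siYT_XMU a (0.015) or b (0.0454).

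Of the 12 histone genes 6 rose with XMU-MP1 in control siRNA and 0 fell (6 adjusted over the list alone, median 1.79, camera adjusted p = 4.31e-13), and this call held with an estimated correlation (adjusted p = 0.0444). H2BC12 rose from 31.8 ± 3.55 to 314 ± 52.8 CPM and H2BC5 from 2.81 ± 0.955 to 51.2 ± 17.8 CPM. Of 23 NF-kB and cytokine genes 9 fell and 0 rose (14 and 1 over the list alone, median -1.60, camera adjusted p = 2.46e-06, adjusted p = 0.261 with an estimated correlation). IL1A, an interleukin, fell from 108 ± 26.3 to 12.8 ± 2.20 CPM, and CXCL1, a chemokine, changed by -2.23. Of 24 ribosome biogenesis genes 7 fell and 0 rose (12 over the list alone, median -0.70, camera adjusted p = 1.69e-05, adjusted p = 0.707 with an estimated correlation). MYC fell from 289 ± 28.3 to 67.4 ± 9.20 CPM (-2.10, adjusted p = 0.000221). Of 24 genes of ATF4 and the unfolded protein response 6 rose and 0 fell (6 and 1 over the list alone and also without siYT_XMU c, median 0.35, camera adjusted p = 0.00788, adjusted p = 0.707 with an estimated correlation). HSPA5, a chaperone of the endoplasmic reticulum, rose from 614 ± 19.2 to 1178 ± 63.1 CPM and ASNS, asparagine synthetase, from 90.1 ± 59.6 to 592 ± 134 CPM. When 1 library was left out, the falls ranged from 4 to 10 for NF-kB and cytokine genes, from 1 to 9 for ribosome biogenesis and from 0 to 1 for ATF4, where the rises ranged from 2 to 6. Fry ended the call of the ATF4 list (adjusted p = 0.133).

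Other lists did not pass camera in control siRNA. Of 30 p63 targets 0 rose and 5 fell (7 over the list alone, camera adjusted p = 0.0542). FAT2, a cadherin, fell from 92.8 ± 4.50 to 17.4 ± 1.59 CPM. Of the 22 YAP and TAZ signature genes 2 rose and 2 fell (3 and 3 over the list alone, camera adjusted p = 0.642), among them FJX1 (-3.05). Of 25 p53 targets 5 rose and 1 fell (8 and 2 over the list alone, 8 and 3 without siYT_XMU c, camera adjusted p = 0.0709), among them CDKN1A, an inhibitor of cell cycle kinases (1.52). With any 1 library left out, 1 to 7 p63 targets fell, 1 to 3 signature genes rose and 1 to 3 fell, and 1 to 8 p53 targets rose and 1 to 3 fell. CCND1, cyclin D1, fell from 197 ± 30.5 to 48.2 ± 9.64 CPM, and ETV5, a transcription factor induced by ERK, rose from 45.7 ± 9.31 to 112 ± 7.69 CPM. YAP1 (-0.59, adjusted p = 0.106), WWTR1 (0.84, adjusted p = 0.278), STK3 (0.10, adjusted p = 0.856), STK4 (0.55, adjusted p = 0.279) and LATS1 (0.48, adjusted p = 0.53) did not pass the test. YAP1 and WWTR1 passed in the fit of the compared groups (adjusted p = 0.00723 and 0.0159), with voom (0.0015 and 0.00218) and on FPKM with a pseudocount of 1 (0.0358 and 0.0287), YAP1 also without siYT_XMU b (0.05) and WWTR1 without siYT_XMU c (0.0318). LATS2 rose by 0.91 (SE 0.25, adjusted p = 0.0484), but this call ended without any 1 of 9 libraries, with an adjusted p between 0.051 and 0.202, and in 6 further settings, with an adjusted p between 0.0567 and 0.0896.

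Among genes whose name is not a bare identifier, with a mean FPKM of at least 5 in the higher group and no overlap of libraries, the largest changes with XMU-MP1 in control siRNA were rises of CCN2, H2BC5 (4.18), H3C4 (3.56), ID2 (3.55), a repressor of helix-loop-helix factors, SERPINI1 (3.49) and H4C15 (3.41). The largest falls by this rule were of ZBED2 (-4.35), MIG7 (-4.34), HCAR2 (-4.22), PRR15L (-4.21), PDGFB (-4.15) and CYP1B1 (-4.13). PDGFB, a growth factor, fell from 22.6 ± 3.18 to 1.27 ± 0.667 CPM and CYP1B1, a cytochrome, from 49.7 ± 14.2 to 2.84 ± 0.752 CPM. The call of ZBED2 ended without any 1 of the 6 control siRNA libraries, with an adjusted p between 0.062 and 0.12. In all, 725 genes rose and 955 fell, 457 and 706 of them by at least 2-fold. The total of 1680 became 816, 749 and 770 without siC_DMSO a, b or c, and 978, 629 and 939 without siC_XMU a, b or c. Without siYT_XMU c, which this comparison does not use but which enters the shared spread, it was 2661, and DESeq2 called 1305 genes higher and 1747 lower.

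XMU-MP1 after the knockdown asks what the inhibitor changed where YAP1 and WWTR1 were low. There FOSB, DUSP2 and ARC rose, and GRHL3, a transcription factor of epidermal differentiation, and IL1A fell. FOSB, a part of the AP-1 factor, rose from 2.51 ± 0.539 to 66.8 ± 40.1 CPM (4.72, adjusted p = 0.000206). DUSP2, a phosphatase of MAP kinases, rose from 2.65 ± 0.915 to 68.2 ± 27.2 CPM (4.70, adjusted p = 8.05e-05), and ARC, an immediate early gene best known in neurons, from 0 counts to 125 ± 91.0 CPM, at least 1610-fold. GRHL3 fell from 248 ± 71.8 to 9.63 ± 1.71 CPM (-4.66, adjusted p = 5.37e-05) and IL1A from 168 ± 68.6 to 5.83 ± 3.63 CPM (-4.74, adjusted p = 0.000182). CCN1 rose from 2.04 ± 0.826 to 38.8 ± 26.2 CPM (4.26, SE 0.59, adjusted p = 0.00103).

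Of 24 immediate early and AP-1 genes 10 rose and 3 fell with XMU-MP1 after the knockdown (11 and 3 adjusted over the list alone, median 0.71, camera adjusted p = 0.00101, adjusted p = 0.224 with an estimated correlation). Of 30 G2/M genes 4 rose and 0 fell (4 over the list alone, median 0.63, camera adjusted p = 0.00466, adjusted p = 0.891 with an estimated correlation). NUSAP1 rose by 1.71 and PTTG1 by 1.25. Of 18 heat shock genes 4 rose and 0 fell (6 over the list alone, median 0.54, camera adjusted p = 0.00316, adjusted p = 0.891 with an estimated correlation). That call ended with total counts (adjusted p = 0.12) and with quantile normalisation (adjusted p = 0.102). The histone list had 1 of 12 genes higher, H2BC12 (1.27, also 1 over the list alone), with a camera adjusted p of 0.015 that became 0.0649 without replicate c of siYT_XMU (adjusted p = 0.891 with an estimated correlation). Hypoxia and glycolysis had 3 higher and 1 lower of 19 (3 and 1 over the list alone, 5 and 1 without siYT_XMU c, camera adjusted p = 0.0423, adjusted p = 0.891 with an estimated correlation). PFKFB3, a regulator of glycolysis, rose by 2.92. The median of the hypoxia list, 0.31, turned to -0.014 with total counts (adjusted p = 0.12) and to -0.13 on FPKM with a pseudocount of 0.1 or 1, and the call also ended with quantile normalisation (adjusted p = 0.248). With any 1 library left out, 1 to 3 immediate early genes fell, and the rises ranged from 2 to 9 for G2/M, 0 to 6 for heat shock, 1 to 2 for histones and 2 to 5 for hypoxia, where 0 to 1 fell. CDK1 and HMMR, of the 4 G2/M genes that rose, each lost the call without any 1 of 10 libraries. Fry ended the list calls of G2/M (adjusted p = 0.493), heat shock and histones (both 0.0545) and hypoxia (0.205), but not that of immediate early genes. MYC fell from 111 ± 17.5 to 14.3 ± 3.05 CPM (-2.98, adjusted p = 2.13e-05), and ETV5 rose from 7.83 ± 2.09 to 62.9 ± 2.37 CPM.

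YAP1 fell by a further 0.90 (adjusted p = 0.0221) and WWTR1 by 1.62 (adjusted p = 0.0463) with XMU-MP1 after the knockdown. The call of YAP1 ended without siYT_DMSO a (adjusted p = 0.0716) or siYT_XMU b (0.0615), and that of WWTR1 without any 1 of 10 libraries (adjusted p between 0.0597 and 0.113). Both ended in the fit of the compared groups (adjusted p = 0.254 and 0.319) and with voom (0.172 and 0.233), and that of WWTR1 also without an abundance trend (0.0552) and with a replicate block (0.056). Of the 22 YAP and TAZ signature genes 4 rose and 3 fell (5 and 3 over the list alone, camera adjusted p = 0.507), or 3 and 5 without siYT_XMU c, where the median of 0.21 turned to -0.16. Of these, 2 to 5 rose and 3 to 5 fell when any 1 library was left out. CCN2 rose by 3.53 (SE 0.90, adjusted p = 0.0264), with levels of 0.968, 6.94 and 18 CPM in siYT_XMU, and its call ended without siYT_DMSO a (0.0514), b (0.0981) or c (0.104) or siYT_XMU c (0.0624). It also ended with quantile normalisation (adjusted p = 0.0622), in the fit of the compared groups (0.0849), on FPKM (log2 fold change 1.17 to 2.17, adjusted p between 0.0611 and 0.16) and with voom (1.88, adjusted p = 0.611). STK3 (0.23, adjusted p = 0.534), STK4 (0.34, adjusted p = 0.506), LATS1 (0.05, adjusted p = 0.966) and LATS2 (-0.46, adjusted p = 0.296) did not pass the test. LATS2 passed with total counts (-0.88, adjusted p = 0.0437) and on FPKM with a pseudocount of 0.1 (-0.78, adjusted p = 0.0448). Besides ARC, the largest rises by the same rule were of ADAMTSL4-AS2, an antisense transcript (at least 155-fold, where the use of strand in counting is not stated), PYGM, muscle glycogen phosphorylase (7.91), RASD1 (7.65), NR4A1, an immediate early nuclear receptor (6.82), and TRS-GCT1-1, a transfer RNA with near-identical copies. TRS-GCT1-1 stood at 0, 0.0773 and 0 CPM in siYT_DMSO and at 1.35, 0.928 and 6.42 CPM in siYT_XMU, and no fold is given against counts so low. PYGM stood at 0, 0.0773 and 0.182 CPM in siYT_DMSO and RASD1 at 0, 0.367 and 0.116 CPM, so their folds rest on few counts. The call of TRS-GCT1-1 ended without siYT_DMSO a (adjusted p = 0.0513) or c (0.0574). The largest falls by it were of DUSP16 (at least 146-fold), TRIM63, THBD, thrombomodulin (-5.29), NIPAL4 (-4.96), IL1A and GRHL3. DUSP16 lost its call without siYT_DMSO c (adjusted p = 0.0526), siYT_XMU a (0.0529) or siYT_XMU b (0.0551), and had 0 counts in siC_DMSO b and in all 6 XMU-MP1 libraries against 9.51 and 8.15 CPM in the other siC_DMSO libraries. As for CHCHD10, such values of 0 need not be an absence of the transcript. TRIM63 stood at 1.54, 3.56 and 30.2 CPM in siYT_DMSO and at 0, 0.232 and 0 CPM in siYT_XMU, with no fold given against counts so low, and lost its call without siYT_DMSO b (0.0505) or c (0.147), or siYT_XMU a (0.0807), b (0.0597) or c (0.0739). In all, 761 genes rose and 1437 fell, 594 and 986 of them by at least 2-fold. The total of 2198 became 1357 and 1159 without siYT_DMSO b or c, the rises became 482 without siYT_DMSO a, and without siYT_XMU c 1277 genes rose and 1608 fell. DESeq2 called 1690 genes higher and 1980 lower.

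The call of TP63 with XMU-MP1 after the knockdown depended on the setting. TP63 stood at 23.9, 10.8 and 19.7 CPM in siYT_DMSO and at 3.58, 3.25 and 12.4 CPM in siYT_XMU, and the change did not pass the edgeR test (-1.58, SE 0.49, adjusted p = 0.0615, exact permutation p = 0.2). With the same 12 libraries it passed with total counts (-2.07, adjusted p = 0.00636), DESeq2 (-1.47, adjusted p = 0.0243), voom (-2.09, adjusted p = 0.0184) and on FPKM with each pseudocount (adjusted p between 0.00264 and 0.00413). It did not pass with no filter, median-ratio size factors, quantile normalisation, the fit of the compared groups or a replicate block. Nor did it pass with the robust variance model or the one without an abundance trend. Total counts and FPKM also lowered the median log2 fold change of all genes in this comparison, to -0.33 and to between -0.47 and -0.35. Without siYT_XMU c TP63 fell by 2.41 on the log2 scale (SE 0.38, adjusted p = 0.0033). The knockdown itself did not change TP63 past the test in DMSO (-0.55, SE 0.47, adjusted p = 0.425, exact permutation p = 0.2) or in XMU-MP1 (0.95, SE 0.49, adjusted p = 0.155, exact permutation p = 0.4). The change in DMSO passed the threshold with voom (-0.71, adjusted p = 0.0354) and on FPKM with a pseudocount of 1 (-0.60, adjusted p = 0.0357). The difference between the arms in the response of TP63 to XMU-MP1 was 1.5 (SE 0.68, adjusted p = 0.271), or 0.67 without siYT_XMU c (SE 0.46, adjusted p = 0.421), and was not called.

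The knockdown in XMU-MP1 asks what the loss of YAP and TAZ changed with the inhibitor present. The epidermal rise and the cell cycle fall seen in DMSO were there too. Of 22 epidermal differentiation genes 19 rose and 0 fell (21 adjusted over the list alone, median 6.20, or 5.97 with bounds, camera adjusted p = 1.1e-26), and this call held with an estimated correlation (adjusted p = 0.0258). All 30 G2/M genes (median -3.72, camera adjusted p = 1.42e-33, adjusted p = 0.0986 with an estimated correlation) and all 28 G1/S genes (median -3.34, camera adjusted p = 1.23e-27, adjusted p = 0.0531 with an estimated correlation) fell, with 30 and 28 also adjusted over the list alone. Of 24 immediate early genes 16 rose and 1 fell (16 and 1 over the list alone, median 1.55, camera adjusted p = 3.45e-09), a call that also held with an estimated correlation (adjusted p = 0.0178). The share of ribosomal RNA was 5.38, 2.65 and 35.0% in siYT_XMU against 2.52, 1.21 and 1.02% in siC_XMU.

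SPRR1B rose by 8.19, S100A7 by 8.20 and DUSP2 by 7.51, and KIF20A fell by 4.53 with the knockdown in XMU-MP1. Of 22 YAP and TAZ signature genes 12 fell and 0 rose (13 adjusted over the list alone, median -1.02, camera adjusted p = 5.25e-05, adjusted p = 0.266 with an estimated correlation). CCN1 fell by 2.44 (adjusted p = 0.00403) and CCN2 by 4.49 (adjusted p = 0.00212). Of 29 Hippo components 2 rose and 15 fell (2 and 18 over the list alone, median -0.91, camera adjusted p = 2.69e-07, adjusted p = 0.109 with an estimated correlation). The siRNA targets YAP1 and WWTR1 are again among these falls and in the camera test. YAP1 fell by 4.70, WWTR1 by 5.43, LATS2 by 3.02 (adjusted p = 1.61e-05) and STK3 by 1.71 (adjusted p = 0.000114). STK4 (-0.48, adjusted p = 0.214) and LATS1 (-0.89, adjusted p = 0.102) did not pass the test. STK4 passed with total counts (adjusted p = 0.0192) and on FPKM (0.0142 to 0.0168), and LATS1 with these (0.000796 to 0.00311), with voom (0.00123) and without siYT_XMU c (-1.66, adjusted p = 0.000342). Of 30 p63 targets 10 rose and 3 fell (11 and 4 over the list alone, camera adjusted p = 0.0181, adjusted p = 0.517 with an estimated correlation), with CSTA higher by 3.70. The median of the p63 list, 0.19, turned to -0.33 with total counts (adjusted p = 0.0954) and to -0.38 and -0.32 on FPKM with a pseudocount of 0.1 and 1, and the call also ended with quantile normalisation (adjusted p = 0.151). Of the 4 leukocyte markers CD68, CD14, ITGAM and CSF1R all rose (4 over the list alone, median 2.42, camera adjusted p = 0.0151, adjusted p = 0.408 with an estimated correlation), CSF1R not being called without siYT_XMU b (1.39, adjusted p = 0.0557). Ribosome biogenesis (0 higher and 11 lower of 24), ATF4 and the unfolded protein response (1 and 14 of 24), p53 targets (3 and 10 of 25), SRF and MRTF targets (2 and 9 of 21), histones (5 and 0 of 12), hypoxia (6 and 0 of 19) and cholesterol synthesis (8 and 1 of 21) also passed camera. Adjusted over the list alone these counts were 0 and 11, 1 and 15, 4 and 11, 2 and 10, 5 and 0, 6 and 0, and 8 and 1. Their camera adjusted p lay between 0.00219 and 0.05 (cholesterol synthesis, at the threshold), and between 0.29 and 0.763 with an estimated correlation. With any 1 library left out, the higher counts ranged from 4 to 10 for hypoxia (10 without siYT_XMU c), 5 to 10 for cholesterol synthesis, 1 to 4 for p53 targets, 1 to 3 for SRF and MRTF targets and 0 to 2 for ATF4. The lower counts ranged from 1 to 4 for p63 targets and 1 to 2 for cholesterol synthesis. The calls of the p53 targets (adjusted p = 0.178 with quantile normalisation), of SRF and MRTF targets (0.0717 with median-ratio size factors), of hypoxia (0.098 with total counts), of cholesterol synthesis (0.249 with total counts, and also with quantile normalisation and on FPKM with a pseudocount of 0.1 or 1, where its median of 0.54 turned to -0.13) and of ATF4 (0.0552 on FPKM with a pseudocount of 1) ended in at least 1 setting. Fry also ended the call of cholesterol synthesis (adjusted p = 0.107). In all, 3219 genes rose and 3381 fell, 2555 and 2429 of them by at least 2-fold, and without siYT_XMU c 3710 rose and 3602 fell.

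The interaction asks whether the response to XMU-MP1 differed between the siRNA arms. DUSP2 and CXCL8 had higher responses after the knockdown, and the histone genes H2BC4 and H2BC5 lower ones. DUSP2 had the smallest adjusted p of the rises named (interaction 6.73, SE 0.53, adjusted p = 0.000578). CXCL8, a chemokine, stood at 17.6 ± 7.98 CPM in siC_DMSO, 3.44 ± 0.323 in siC_XMU, 8.26 ± 5.52 in siYT_DMSO and 68.5 ± 23.9 in siYT_XMU (5.40, SE 0.78, adjusted p = 0.00795). CCND1 fell with XMU-MP1 in control siRNA and stood at 93.9 ± 30.2 CPM in siYT_DMSO and 123 ± 38.5 CPM in siYT_XMU (2.41, adjusted p = 0.0137).

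Of 23 NF-kB and cytokine genes 4 had higher and 0 lower responses after the knockdown (7 and 1 adjusted over the list alone, median 1.06, camera adjusted p = 8.36e-05, adjusted p = 0.365 with an estimated correlation). Of 24 immediate early genes 7 were higher and 0 lower (10 and 3 over the list alone, 6 and 2 without siYT_XMU c, camera adjusted p = 0.000376, adjusted p = 0.203 with an estimated correlation), among them FOSB (3.95) and IER3 (2.06). The list's median of 0.14 turned to -0.14 with total counts, to -0.33 and -0.32 on FPKM with a pseudocount of 0.1 and 1, and to -0.045 with quantile normalisation, where the call ended (adjusted p = 0.105). Of 12 histone genes 5 were lower and 0 higher (5 over the list alone, median -0.74, camera adjusted p = 0.000265, adjusted p = 0.365 with an estimated correlation), among them H2BC4 (-3.09) and H2BC5 (-3.35). That call ended on FPKM with a pseudocount of 0.1 (adjusted p = 0.192) or 1 (adjusted p = 0.173). Ribosome biogenesis had 3 higher and 0 lower of 24 (7 over the list alone, 5 without siYT_XMU c, median 0.74, camera adjusted p = 6.41e-06, adjusted p = 0.65 with an estimated correlation). Hippo components had 1 lower of 29 (5 over the list alone, 5 of 30 without siYT_XMU c, median -0.43, camera adjusted p = 0.00485, adjusted p = 0.65 with an estimated correlation). Its call ended with quantile normalisation (adjusted p = 0.095). Basal mammary markers had 0 of 21 called (0 over the list alone, median 0.74, camera adjusted p = 0.00485, adjusted p = 0.664 with an estimated correlation). This call ended without siYT_XMU c (adjusted p = 0.083). Fry ended the calls of NF-kB and cytokine genes and of histones (both adjusted p = 0.0536). It also ended those of ribosome biogenesis (adjusted p = 0.0809), Hippo components (0.076) and basal markers (0.228), but not that of immediate early genes. The counts of list members changed when single libraries were left out, and of 28 named genes called for the interaction 18 lost the call without at least 1 library. With any 1 library left out, the higher counts ranged from 1 to 5 for NF-kB and cytokine genes, 3 to 7 for immediate early genes and 0 to 5 for ribosome biogenesis. The lower counts ranged from 0 to 2 for immediate early genes, 2 to 5 for histones and 0 to 5 for Hippo components. CCN1 (2.60, adjusted p = 0.0843), CCN2 (-1.26, adjusted p = 0.624), WWTR1 (-2.46, adjusted p = 0.0664), LATS2 (-1.37, adjusted p = 0.0735), YAP1 (-0.31, adjusted p = 0.655), STK3 (0.13, adjusted p = 0.883), STK4 (-0.22, adjusted p = 0.85) and LATS1 (-0.43, adjusted p = 0.756) were not called. DESeq2 called CCN1 (adjusted p = 0.00539), WWTR1 (0.00017) and LATS2 (0.00961). WWTR1 was also called with no filter, on FPKM and without siYT_XMU a or c (adjusted p between 0.0132 and 0.0476), and LATS2 with total counts, on FPKM, with voom and without siYT_XMU c (0.0227 to 0.0462). Without siYT_XMU a CCN1 was called (0.0152), and without siYT_XMU c LATS1 was (0.0464). In all, 156 genes had higher and 314 lower responses after the knockdown, 151 and 301 of them by at least 2-fold. The total of 470 became 156, 86 and 91 without siC_DMSO a, b or c, 100 and 96 without siC_XMU b or c, 96 and 118 without siYT_DMSO b or c, and 1006 without siYT_XMU c. An unadjusted p under 0.05 was reached by 3324 genes, and DESeq2 called 854 higher and 949 lower.

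**Figure D4:**
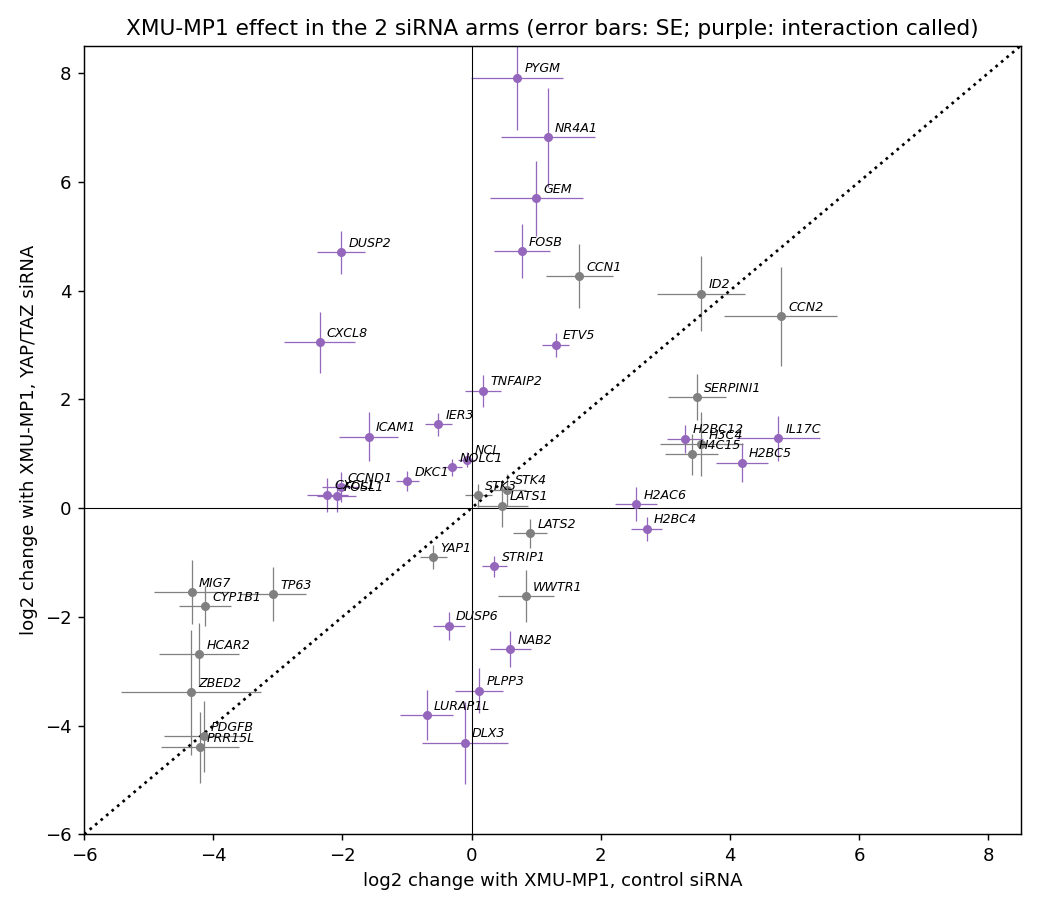
Log2 fold change with XMU-MP1 in control siRNA (horizontal) and after the knockdown (vertical) for the named genes, each ± SE, with genes called for the interaction in purple. CXCL8 lies far above the diagonal (interaction 5.40) and H2BC5 below it (-3.35).

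The responses to XMU-MP1 in the siRNA arms, which share no library, overlapped. Of the called genes 215 rose in both arms, against 30.4 for independent lists, and 342 fell in both, against 75.6. Opposite directions were seen for 28 genes (57.4 for independent lists) and 8 genes (40.1). Of the 1680 genes called in control siRNA, 80.2% had the same sign after the knockdown, and 214 were called for the interaction. Of the 2198 genes called after the knockdown, 75.1% had the same sign in control siRNA, and 304 were called for the interaction. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.309 and Spearman's rho 0.329. TP63 was among the genes called in control siRNA, and IL1A, MYC and ETV5 were called in both arms in the same direction.

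The knockdown in DMSO and XMU-MP1 in control siRNA also overlapped, though both use the siC_DMSO libraries. Of the called genes 322 rose in both (117 for independent lists), 301 fell in both (152), 218 rose with the knockdown and fell with XMU-MP1 (154), and 89 did the reverse (116). MYC fell in both, H2BC5 rose in both, and CCN2 fell with the knockdown and rose with XMU-MP1. In 20 simulations of unchanged groups against shared controls the log2 fold changes had a covariance of 0.467, against 0.759 here. Pearson's r across genes was 0.229 here against 0.484 in the simulations, and 57.3% of genes had the same sign against 66.4%. The difference of the covariances, 0.293, is a rough estimate of the part that the shared libraries do not give. Differences of r or of the share of equal signs give no such estimate. The simulated spread was taken from all 4 groups. Replicates of siC_DMSO lay closer together (Pearson's r of log2 CPM between 0.962 and 0.969) than those of siYT_XMU (between 0.852 and 0.934). The simulated covariance may thus be too high. The 3 controls cannot be split so that each part keeps 2 libraries, so for the counts of genes the part that comes from the shared libraries is not known.

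The balance of rises and falls differed between settings, some of which change the test as well as the scaling. With TMM the median log2 fold change of all genes was 0.02, -0.02, 0.02, 0.04 and 0.07 in the knockdown in DMSO, XMU-MP1 in control siRNA, XMU-MP1 after the knockdown, the knockdown in XMU-MP1 and the interaction, and rises made up 50.3, 43.2, 34.6, 48.8 and 33.2% of the calls. With total counts the medians were -0.15, -0.10, -0.33, -0.41 and -0.20 and the shares 39.6, 30.7, 16.3, 28.3 and 20.4%. On FPKM with a pseudocount of 0.5 the medians were -0.20, -0.07, -0.40, -0.60 and -0.31 and the shares 34.7, 28.7, 9.90, 18.3 and 17.9%. The shares for XMU-MP1 after the knockdown and for the interaction were 46.0 and 47.4% with DESeq2, 45.3 and 47.7% with quantile normalisation, 41.4 and 40.7% with median-ratio size factors and 41.0 and 40.5% with voom, which used TMM. Both DESeq2 and median-ratio size factors gave medians of 0.13 for the knockdown in XMU-MP1 and 0.14 for the interaction.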

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

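The tests of library c of siYT_XMU, of the scaling and of the interaction by relabelling were put in their present form after the results were seen, while the splits of the 4 group comparisons were set before. The 12 genes below drew attention because the response to XMU-MP1 differed between the siRNA arms by the test of the interaction itself, and so did the number of genes called for it, 470.

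Among called genes whose name is not a bare identifier, with a mean FPKM of at least 5 in the highest group, the 6 largest positive interaction terms were those of PYGM (7.21), PGLYRP4 (7.19, with 0 counts in siC_XMU, so that its size rests on the prior count), DUSP2 (6.73), NR4A1 (5.64), CXCL8 (5.40) and GEM (4.69). DUSP2 and NR4A1 belong to the list of immediate early genes, and PGLYRP4 stood at 31.5 to 34.5 CPM in siYT_DMSO and 32.9 to 45.9 CPM in siYT_XMU.

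Of the 24 immediate early genes 7 had a called, higher response to XMU-MP1 after the knockdown. Against the shallow library siYT_XMU c as the source, 6 of the 24 had a called, higher response without it, all 6 among these 7, and the list passed camera (adjusted p = 0.0204). A lower response was then called for 2, against 0 with it, and with all 12 libraries the list did not pass with an estimated correlation (adjusted p = 0.203). The scaling stays open as a source, since the list's median term of 0.14 became -0.14 with total counts, where 4 genes were called and the list passed (adjusted p = 0.00259), and the list did not pass with quantile normalisation (adjusted p = 0.105). Leaving out other single libraries took the 7 called genes to as few as 3. A difference in the number of cells between the arms stays open too, for which the table holds no measure. So does a difference in their state, which the knockdown lists show in DMSO (epidermal median 5.41, G2/M median -4.22), since its part in this response was not tested. A difference of the signalling response without YAP and TAZ may be the biological source but was not tested.

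By the same rule the 6 largest negative terms were those of DLX3 (-4.21), PLPP3 (-3.47), IL17C (-3.46), H2BC5 (-3.35), NAB2 (-3.20) and LURAP1L (-3.12). The calls of PYGM, DUSP2, CXCL8, PLPP3, H2BC5 and NAB2 were kept without any 1 library. Calls of the other 6 ended without several of the libraries, and the highest adjusted p was 0.11 for PGLYRP4 without siC_XMU c, 0.0794 for NR4A1 without siYT_DMSO b, 0.14 for GEM and 0.127 for DLX3 without siC_DMSO c, 0.101 for IL17C without siC_DMSO b and 0.0758 for LURAP1L without siC_DMSO c. The term of IL17C was -6.52 without siC_DMSO c, and since its siC_DMSO levels were 0, 0 and 0.0551 CPM, its size rests on the prior count.

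For the number of genes called, 50 relabellings of the treatment within each siRNA arm were counted, the real one included, and 2 gave as many genes. The real labels gave 470 genes, and the highest other relabelling gave 3201. That relabelling keeps the control arm and exchanges all treatments in the knockdown arm, so its contrast is the sum of both responses and not their difference. Mixed labels also put the treatment effects of each arm (1680 and 2198 genes) into the spread, so this count does not test the interaction, and whether chance gives as many genes is left open. For the other comparisons the 10 splits of 6 libraries are too few for a share under 0.05. Every split but the real one mixes libraries of both groups, which puts the difference between them into the spread. The counts of those splits are therefore no measure of what chance gives. The real split was 1 of 10 to reach its number in each of the 4: 5826 genes for the knockdown in DMSO (highest other 0), 1680 for XMU-MP1 in control siRNA (highest other 0), 2198 for XMU-MP1 after the knockdown (highest other 12) and 6600 for the knockdown in XMU-MP1 (highest other 1).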

How the results depend on the processing

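The voom setting and the one without ribosomal genes were chosen after the data were seen. Limma-trend on FPKM was planned as the main test for a table without counts, and became an alternative, with the planned pseudocounts, once the table was seen to hold counts. The other settings were planned, and the scaling without TMM was done as total counts. Of 456 results, 454 kept direction and side of the threshold with median-ratio size factors, 439 with quantile normalisation and 451 with a replicate block, where 2, 16 and 5 with the same direction no longer passed. These 456 leave out the gene totals, the overlaps in the same direction, and TP63 with XMU-MP1 in either arm and for the interaction. Changes in those are given below. Without ribosomal genes all 416 results recomputed were kept. With total counts 397 stayed and 52 no longer passed, with DESeq2 407 and 1, and in the fit of only the compared groups 333 and 40. Of 40 list calls 3 held with an estimated correlation and 29 with fry. In simulations that changed few genes, 2-fold changes were called in at most 18% of genes in group comparisons and 0% for the interaction. These shares may be too low where many more genes change. Depth limits what levels can be told from 0: a count of 0 allows up to 0.622 CPM in siYT_XMU c, the highest, and up to 0.0382 CPM in siC_DMSO b, the lowest.

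For the values that changed, the cause was not tested, except that fewer libraries entered where one was left out or only the compared groups were fitted. Leaving out 1 library also redid the filter, so between 18984 and 19433 genes were tested there, against 18143 in the main setting. FPKM values below are for pseudocounts of 0.5, 0.1 and 1. Rises in the knockdown in DMSO were 1909 with total counts and 1645, 1554 and 1681 on FPKM. With XMU-MP1 in control siRNA, rises were 288 with total counts, 1843 in the fit of the compared groups, 1305 with DESeq2, 350, 272 and 409 on FPKM and 2186 with voom, and falls were 2024 in the fit of the compared groups, 1747 with DESeq2, 629 on FPKM with 0.1 and 2866 with voom. With XMU-MP1 after the knockdown, rises were 416 with total counts, 1198 with quantile normalisation, 281 in the fit of the compared groups, 1690 with DESeq2 and 297, 290 and 295 on FPKM, and falls were 496 in the fit of the compared groups and 2703, 2584 and 2692 on FPKM. In the knockdown in XMU-MP1, rises were 2116 with the filter on FPKM of at least 5, 1898 with total counts and 1171, 1151 and 1165 on FPKM, and falls were 2122 with that filter and 5213, 5118 and 5221 on FPKM. For the interaction, higher responses were 253 with the filter, 54 with total counts, 398 with quantile normalisation, 854 with DESeq2, 93 and 51 on FPKM with 0.5 and 0.1 and 494 with voom, and lower ones 949 with DESeq2, 541 on FPKM with 1 and 726 with voom. Genes that rose with XMU-MP1 in both arms were 86 with total counts, 324 with quantile normalisation, 464 with DESeq2, 92, 89 and 94 on FPKM and 367 with voom, and genes that fell in both were 607, 549 and 547 with DESeq2, FPKM with 1 and voom. Genes that rose with both the knockdown and XMU-MP1 were 120 with total counts, 588 with DESeq2, 92, 89 and 85 on FPKM and 808 with voom, and genes that fell with both were 605, 563 and 1316 with DESeq2, FPKM with 1 and voom.

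TP63 with XMU-MP1 after the knockdown passed the threshold with total counts (-2.07), DESeq2 (-1.47), FPKM (-1.44, -1.93 and -1.11), voom (-2.09) and without siYT_XMU c (-2.41), with adjusted p between 0.00264 and 0.0243 there, against 0.0615 in the main setting. The interaction reversed for PGLYRP4 on FPKM with 0.5 (-0.063) and 1 (-0.12) and for IL17C on FPKM with 1 (0.24).

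Over the settings that leave out 1 library, rises and falls ranged from 2191 to 3487 and 2241 to 3612 in the knockdown in DMSO, from 260 to 1134 and 369 to 1527 with XMU-MP1 in control siRNA, from 372 to 1277 and 787 to 1608 with XMU-MP1 after the knockdown, from 2307 to 3710 and 2589 to 3602 in the knockdown in XMU-MP1, and from 32 to 398 and 54 to 608 for the interaction. Genes that rose or fell with XMU-MP1 in both arms ranged from 104 to 314 and from 151 to 501, and genes that rose or fell with both the knockdown and XMU-MP1 from 126 to 502 and from 98 to 585. TP63 ranged from -3.34 to -2.88 with XMU-MP1 in control siRNA, from -2.41 to -1.25 with XMU-MP1 after the knockdown and from 0.67 to 1.83 for the interaction. Of the named genes called with XMU-MP1, 42 of 62 in control siRNA and 61 of 87 after the knockdown kept the call without each library. For the interaction 10 of 28 did, and for the knockdown 107 of 108 in DMSO and 103 of 104 in XMU-MP1.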

Other observations

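The GO terms below, the genes named from them, and the tests of leukocyte reads and of TP63 were chosen after the results were seen. The prediction for the ribosomal RNA share is recorded as set before its test. Its pattern and its use of SLCO5A1 come from these data, however, so that test was not fixed before the data were examined. The terms are those given in the table, 2037 of them with 15 to 500 genes, against the 16532 tested genes that carry a term, and the genes named from them were not carried through the alternatives.

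Many genes of lysosomes and autophagy rose after the knockdown in DMSO. Of 224 genes of the lysosomal membrane 92 rose, against 37.8 for a random draw (adjusted p = 1.22e-14), among them RAB7A (1.82), a GTPase of late endosomes. Of 42 genes of autophagosome assembly 27 rose, against 7.09 (adjusted p = 2.51e-09), among them ATG13 (1.64) and STX12 (2.42), and of 84 genes of the late endosome membrane 40 rose, against 14.2 (adjusted p = 1.54e-08), among them MCOLN1 (2.39), a calcium channel of lysosomes. Of 203 genes of DNA repair 86 fell, against 34.6 (adjusted p = 4.74e-15), among them PARP1 (-3.35) and MSH6 (-2.50). In the knockdown in XMU-MP1 19 of 31 genes of transferrin transport rose, against 5.53 (adjusted p = 1.48e-05), among them STEAP3 (1.66), an iron reductase.

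Other terms held genes that fell with XMU-MP1. In control siRNA 40 of 240 genes of the inflammatory response fell, against 13.3 (adjusted p = 7.85e-07), among them BDKRB2 (-4.97), a bradykinin receptor, and 9 of 19 genes that promote migration of smooth muscle cells, against 1.06 (adjusted p = 0.000183), among them PLAU (-3.32), urokinase, and PDGFB (-4.15). After the knockdown 80 of 416 genes of transcription by RNA polymerase II fell, against 35.6 (adjusted p = 7.48e-09), among them CEBPB (-2.27) and EHF (-2.20), which are transcription factors of epithelial cells. This term also passed for the interaction, where 23 of its genes had lower responses after the knockdown, against 7.85 (adjusted p = 0.00904). The inflammatory and migration terms did not pass for the interaction, but cytokine-mediated signalling did. Of its 187 genes 30 fell with XMU-MP1 in control siRNA, against 10.4 (adjusted p = 0.000147). For the interaction 9 of them had higher responses after the knockdown, against 1.70 (adjusted p = 0.0269).

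The rise of differentiation genes and the fall of mitotic genes after the knockdown came with more ribosomal RNA in those libraries. Against the ribosomal share and depth as the source, the median log2 fold change of the epidermal list was 5.94 (19 of 22 genes higher) and that of the G2/M list -4.80 (30 of 30 lower) when only siYT_DMSO c and siYT_XMU b, whose share of ribosomal RNA and SLCO5A1 lay inside the range of the 6 control siRNA libraries (1.28 to 3.75%), were compared with those 6. Against reads from leukocytes behind S100A8 and S100A9, PTPRC, which nearly all leukocytes make, stood at 0.0258 CPM in siYT_DMSO and LYZ, which myeloid cells make, at 0 CPM, where S100A9 stood at 7113 ± 1867 CPM. The summed level of the 10 leukocyte genes of the list was 1.80% of that of S100A9, and CD68, a lysosomal protein that other cells make too, gave most of it (78.8 ± 28.8 CPM). Entry into differentiation with exit from the cell cycle upon loss of YAP and TAZ is a hypothesis that may account for the pattern. To decide it, cell cycle and differentiation would have to be measured at matched cell density, with and without YAP and TAZ that the siRNA cannot target, none of which is in the series. A change of cell density after the siRNA stays open as well, since the table holds no measure of it.

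TP63 fell less with XMU-MP1 after the knockdown than in control siRNA, by a difference that was not called. With all 12 libraries the fall after the knockdown was -1.58 (SE 0.49, adjusted p = 0.0615, exact permutation p = 0.2) and was not called. Whether the fall needs YAP and TAZ stays open. Without siYT_XMU c, whose TP63 level was the highest of its group, the value was -2.41 (SE 0.38, adjusted p = 0.0033). That test was chosen after the results were seen. With all 12 libraries some settings called the fall, such as DESeq2 (-1.47, adjusted p = 0.0243). Others did not, such as median-ratio size factors and quantile normalisation. The targeted transcripts were also not fully removed in siYT_XMU. YAP1 stood there at 5.28 ± 1.42 CPM and WWTR1 at 1.12 ± 1.06 CPM, with no count of WWTR1 in library c. Whether siYT_XMU c makes the difference cannot be told apart from a real one, since without it the interaction was 0.67 (SE 0.46), larger than its SE and not past the threshold. The data are thus consistent with a fall of TP63 in both arms, which is a hypothesis. In simulated data with few genes changed, the interaction test called 0% of 2-fold and 36% of 4-fold differences, shares that may be too low for these data. The levels do not separate the TA and deltaN transcripts, and a second inhibitor or an siRNA against STK3 and STK4, neither of which is in the series, would be needed to tie the fall to MST1 and MST2.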
